A study of Arabidopsis with 9 samples.

How the data were processed

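Total RNA of 14-day-old seedlings, 3 biological replicates per genotype, was sequenced as paired reads on a NovaSeq instrument, per the labels' protocols. The submitters' processing notes name TopHat2 2.1.1, Cufflinks 2.1.1, Cuffdiff 2.1.1 and the TAIR10 genome. Their settings and the strandedness of the libraries are not given in the sources used here. Without strand, reads of overlapping or antisense genes cannot be told apart. The authors deposited FPKM values, fragment counts scaled to transcript length and sequencing depth, as 1 pooled value per locus and condition, per the file headers. Per the file headers, the deposited test statistic is a score for each locus and comparison. The deposited p-value and q-value belong to the authors' comparison of syd-5 or the unlabelled condition with WT.

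The table has 63494 entries for 31747 loci, each in 2 comparisons, with the same WT value in both. The table's status field marks 19236 loci as tested in syd-5 and 19233 in the unlabelled condition. A further 12508 and 12512 were not tested, 2 in each had too many reads, and 1 in syd-5 failed. The authors' own flag of a significant change equals a tested status with q < 0.05 in all 63494 entries. The smallest p in the table is 5e-05 and the smallest q 0.000567, so many loci share it (2611 of the calls in syd-5 and 2622 in the unlabelled condition). That q is 1.55 times what a Benjamini-Hochberg adjustment over the 38469 tests in the table gives, so the authors adjusted over a larger family or in another way.

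Genes have 33553 identifiers in the table, of which 32806 were matched by locus tag to a RefSeq gene table of the TAIR10.1 assembly, used for symbols alone. Genes without a symbol there keep their identifier. Locus starts in the table were raised by 1 to count from 1, since 36.4% of 28922 single-gene loci then start where the reference gene does, against 0.380% without it. At 2056 loci several gene names are merged and their reads cannot be split, and 156 have no name. Where a gene is at several loci, the locus with the highest mean FPKM was taken.

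Before the data were examined, a moderated linear model in limma on values per library had been chosen, with the authors' own p and q as the fallback for a table of group values. The model could not be used, because the table holds no value per library, so the authors' q with a threshold of 0.05 gave the calls and no further test was run against WT. Loci with at least 1 FPKM in at least 1 condition were kept, 18505 in all. Log2 fold changes are on the scale of log2(FPKM + 1), which understates the change of low genes. The log2 ratios named as such have no pseudocount. The standard error of such a ratio was taken as its size over the test statistic. The normal deviate of the authors' p was a median 1.74 times the statistic, so the errors behind p are smaller by that factor. For the unlabelled condition against syd-5, the difference of the log2 ratios was divided by the root of the summed squared errors on the scale of p, two-sided, with Benjamini-Hochberg adjustment. The WT error enters both ratios and is counted in both, so this test is conservative for it. On simulated data for that comparison, over 18382 loci with 200 changed, it recovered 58.5% of changes of 1 in log2 and 88.5% of changes of 2, with 0 false calls. The simulated noise had the errors that the test itself assumes, on the scale of p. It therefore cannot show whether that scale is right, and the low number of false calls follows from the construction.

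There are 24 gene lists fixed before the data were examined. For each the members past the threshold were counted, over all loci and with p adjusted over the list alone, and the median was placed among 10000 random lists of the same size, matched on mean FPKM in 20 bins. In a test on simulated lists of 20 loci in syd-5, 40 of 40 lists shifted by 0.5 lay above percentile 97.5 and 0 of 40 unshifted lists lay outside the central 95%. Random lists take loci as independent, which co-regulated genes are not. The rule for named genes was fixed at the same time. It takes SYD and SWI3D, the 8 largest rises and 8 largest falls per condition among called loci with a mean of at least 5 FPKM, and the 3 called members with the smallest q in each list with at least 3 called, ties going to the larger fold change. Between the conditions it takes the 5 largest differences each way. Some genes that the rule takes are not reported here. Members named for lists with fewer calls, and the examples named from the lists of the closing part, were chosen after their values were seen. The lists of the closing part were drawn up after the leading genes were seen and before the values of their other members were. The alternatives were a pseudocount of 0.1, no filter, a filter of 5 FPKM, quantile normalization of the 3 conditions, a doubling or halving as an added condition, and q < 0.01. Those chosen after the data were seen were an adjustment within each comparison, loci with 1 gene name, ratios without a pseudocount, and other error scales, also for the simulated covariance. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.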

Results

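Gene expression was measured by RNA sequencing in 14-day-old Arabidopsis seedlings grown in long days. The labels give 9 samples, 3 biological replicates each of the wild type (WT), syd-5 and swi3d-1. SYD is an ATPase and SWI3D a core subunit of SWI/SNF complexes, which remodel chromatin by moving nucleosomes. The values came from the authors' deposited table, which holds 31747 loci, each with 1 pooled FPKM for each of 3 conditions and with the authors' test of 2 conditions against WT. Its conditions are WT, syd-5 and a further one whose name ends in 3d and matches no label, called the unlabelled condition here. The genotype swi3d-1 is the only labelled genotype without an entry of its name, but the table does not say that they are the same. The table used here gives no value per replicate and no read depth, so no spread between replicates, interval or detection floor could be computed. The error of a value is known only through the authors' test statistic, from which a standard error of each log2 ratio was derived. Its median was 0.295 in syd-5 and 0.294 in the unlabelled condition. It was 0.614 for syd-5 in the fifth of loci with the lowest mean FPKM and 0.229 in the fifth with the highest, so changes of weakly expressed genes are known less precisely.

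The targeted genes were examined first. In the authors' deposited table SYD (AT2G28290, chromosome 2, 12054736 to 12073412, TAIR10) had 23.1 FPKM in WT, 4.11 in syd-5 and 24.3 in the unlabelled condition. Its log2 ratio to WT was -2.49 in syd-5, with an implied standard error of 0.239 (q = 0.000567), and 0.08 in the unlabelled condition (q = 0.767). SWI3D (AT4G34430, chromosome 4, 16460914 to 16465361) had 16.4 FPKM in WT, 16.0 in syd-5 and 3.81 in the unlabelled condition. Its log2 ratio was -2.11 in the unlabelled condition, with an implied standard error of 0.336 (q = 0.000567), and -0.03 in syd-5 (q = 0.903). These levels were not used to assign the unlabelled condition to a genotype.

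**Figure D1:**
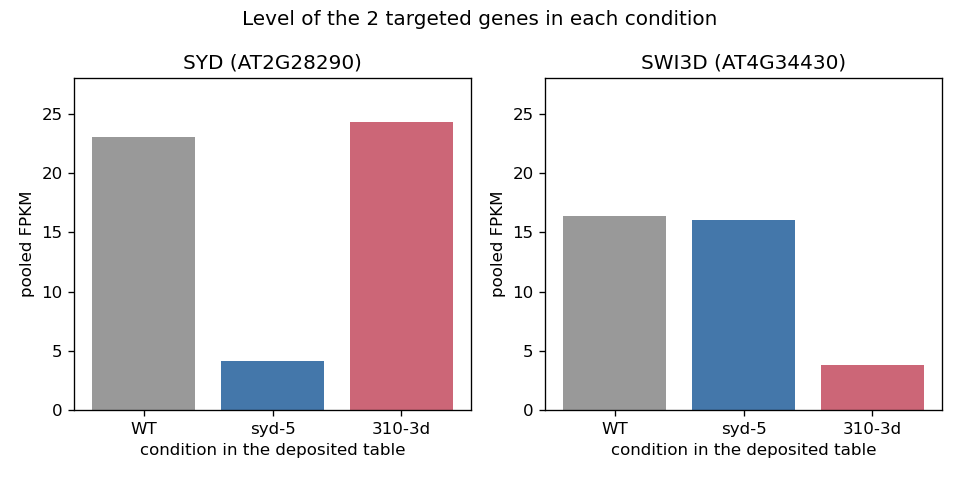
Pooled FPKM (vertical axis) of SYD on the left and SWI3D on the right in the 3 conditions of the authors' deposited table, 1 bar per condition, the unlabelled condition standing last under its name in the table, with no error bars because the table gives no value per replicate. SYD stands at 4.11 FPKM in syd-5 against 23.1 in WT, and SWI3D at 3.81 in the unlabelled condition against 16.4 in WT.

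The comparison of syd-5 with WT asks which transcripts change in that mutant. In the authors' deposited table ASN1, a dark-inducible asparagine synthetase, rose from 1.12 FPKM in WT to 78.7 in syd-5 (log2 fold change 5.23). SEN1, a gene induced in darkness and senescence, rose from 21.6 to 376 FPKM (4.06). The other large rises among loci with a mean of at least 5 FPKM were AT4G12735 (3.78), PHI-1 (3.78), the high-affinity potassium transporter gene HAK5 (3.58), the cell wall enzyme gene TCH4 (3.47), AT3G19680 (3.29) and AT1G70880 (3.28). The largest falls were AT2G30766 (-4.90, from 199 to 5.70 FPKM) and the microRNA precursor MIR157c (-4.80, from 140.1 to 4.05 FPKM). They were followed by LSU3 (-3.85) and LSU1 (-3.74), both known for induction by low sulphur, the phosphate starvation genes PS2 (-3.82) and IPS1 (-3.55), and AT1G47400 (-3.76) and AT1G47395 (-3.46). AT2G30766, AT1G47400 and AT1G47395 encode small peptides induced by iron deficiency. The log2 ratios of AT2G30766, AT1G47400, LSU3 and LSU1 had implied standard errors of 1.57, 1.26, 1.23 and 1.18, against a median of 0.295. The size of these falls is therefore known less precisely. In all, 5143 of 18442 tested loci passed q < 0.05, or 27.9%. Of these, 2551 rose, with a median log2 fold change of 0.68, and 2592 fell, with a median of -0.65. A doubling was reached by 671 and a halving by 580 of them. The authors' test statistic rests on the replicates, which cannot be examined in this table.

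Calls in the hormone lists went in both directions in syd-5 in the authors' deposited table. The medians of the ethylene, salicylic acid and brassinosteroid lists lay within the central 95% of random lists. Of 21 tested genes of jasmonate biosynthesis and response, 12 rose and 0 fell (12 and 1 when adjusted over the list alone), with a median log2 fold change of 0.35 at percentile 99.98 of 10000 random lists matched on expression. VSP2, a vegetative storage protein gene induced by jasmonate, rose from 2.48 to 30.3 FPKM (3.17), JAZ5 by 1.38 and the lipoxygenase gene LOX4 by 1.05. Among 16 tested loci of abscisic acid and cold, 8 rose and 2 fell (8 and 2 over the list alone, median 0.38, percentile 99.92). The genes RD29A and RD29B share 1 merged locus, which rose. COR15A rose by 1.83, HAI1, a phosphatase gene of abscisic acid signalling, by 1.56 and KIN2 by 1.498. Auxin genes went mostly the other way. Of 24 tested, 12 fell and 3 rose (15 and 4 over the list alone; median -0.57, percentile 0), with WES1, which conjugates auxin, at -1.16 among the falls, and GH3.3 (2.31) and SHY2 (1.08) among the rises. Of 14 gibberellin genes 7 fell and 1 rose (7 and 1 over the list alone; median -0.49, percentile 0.02). The gibberellin synthesis genes GA3OX2 (-1.31) and GA3OX1 (-1.24) and GASA6 (-1.21) were among the falls. Of 12 cytokinin response genes 5 rose and 2 fell (6 and 3 over the list alone; median 0.36, percentile 99.34), with ARR6 at 1.55, RR5 at 1.05 and RR16 at -2.95. The ethylene list had 6 falls and 1 rise among 13 (6 and 1 over the list alone; median -0.26, percentile 2.66, but -0.39 and 0.33 over loci with 1 gene name), with PR4 at -0.78 and EBF2 at -0.66. In the salicylic acid and immunity list 7 of 22 rose and 6 fell (8 and 6 over the list alone; median 0.04, percentile 60.54). PR5 (2.82), PR1 (2.71) and BGL2 (1.32), which encode defence proteins, were among the rises. The 6 falls, added outside the rule for named genes, were SNC1 (-0.91), CBP60G (-0.90), WRKY46 (-0.79), WRKY70 (-0.72), ICS1 (-0.57) and PAD4 (-0.53). Of 6 brassinosteroid genes 2 rose and 2 fell (2 and 2 over the list alone; median 0.24, percentile 87.86), with DWF4 at 0.93, BR6OX1 at 0.65 and CPD at -0.49.

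Most calls in the developmental lists were falls in syd-5. In the authors' deposited table, 10 of 15 stomatal lineage genes fell and 0 rose (11 and 0 over the list alone; median -0.75, percentile 0). Root markers, whose level may reflect the share of root tissue, had 8 rises and 1 fall in the same comparison (median 0.32, percentile 99.74). That share was not measured, and a part of it in the fall of the stomatal genes was not tested. The transcription factor gene SPCH, which starts the lineage, fell from 9.39 to 2.54 FPKM (-1.55), and EPF2 and SDD1 fell by 1.12 and 1.09. Of 20 meristem and leaf polarity genes 8 fell and 4 rose (9 and 5 over the list alone; median -0.26, percentile 0.35, but 3.42 with no filter on FPKM), with TCP4 (-1.09), TCP2 (-1.04) and KNAT1 (-0.70) among the falls. Of 25 cell cycle and DNA replication genes 10 fell and 0 rose (11 and 0 over the list alone; median -0.07, percentile 16.61), among them TSO2 (-0.91), MCM3 (-0.70) and MCM2 (-0.68), which serve DNA synthesis. The median of this list was -0.19 (percentile 1.21) with a filter of 5 FPKM and -0.34 (percentile 0.05) over loci with 1 gene name. In the flowering time list 2 of 13 rose and 2 fell (3 and 2 over the list alone; median 0.27, percentile 97.7, but 93.25 with no filter on FPKM). The floral repressor gene FLC rose from 3.89 to 8.53 FPKM (0.96) and MAF5 by 1.70, while AGL24, a promoter of flowering, fell from 17.5 to 2.06 FPKM (-2.60). Of 4 tested floral organ identity genes 1 rose (1 over the list alone; median 0.44, percentile 93.08), and of 3 tested seed maturation genes 1 rose (1 over the list alone; median 0.52, percentile 90.47). With a pseudocount of 0.1 these medians were 1.32 (percentile 99.23) and 1.71 (percentile 98.68), and that of floral organ identity was 1.32 (percentile 99.63) over the 2 genes that reached 5 FPKM. A smaller pseudocount enlarges the change of barely expressed genes. Among them were AP3 (0.08 FPKM in WT, 1.08 in syd-5, q = 0.137) and CRU1 (0.11 and 0.59). The seed maturation genes CRU1 and CRU3 reached 1 FPKM only in the unlabelled condition. Vegetative phase change genes had 2 rises among 11 and 0 falls (2 and 0 over the list alone; median -0.09, mean 0.05, percentile 19.68).

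Calls among heat shock genes in syd-5 were rises. In the authors' deposited table, 9 of 16 rose and 0 fell (11 and 1 over the list alone; median 0.97, percentile 100), with HSP17.6II at 2.55. AT5G51440, which shares a merged locus with RIN3 and RGF5, stood at 2.14, and HSP90.1, merged with MEF1, at 1.92. Reads of a merged locus cannot be split between its genes. Of 16 flavonoid and anthocyanin genes 8 fell and 2 rose (9 and 3 over the list alone; median -0.37, percentile 0.12), with MYB111 (-1.80), MYB90 (-1.66) and TT7 (-1.56) among the falls. Of 18 glucosinolate loci 8 rose and 1 fell (9 and 2 over the list alone; median 0.27, percentile 99.8). The rises included MAM1 (1.22), IMS2 (1.07) and CYP79B3 (0.91), enzymes of that pathway. Light harvesting and Rubisco small subunit genes had 3 rises and 2 falls among 22 (3 and 2 over the list alone; median -0.01, percentile 76.92, but 0.12 and 97.84 over loci with 1 gene name), with RBCS2B at -0.96, LHCB4.3 at -0.74 and LHB1B2 at 0.70. The near-identical copies in this family share reads, so single members are uncertain. Clock genes had 1 rise and 4 falls among 19 (1 and 5 over the list alone; median -0.17, percentile 5.28, but 2.34 over loci with 1 gene name), with ELF4 at -0.87, PCL1 at 0.81 and RVE1 at -0.65. Root markers had 8 rises and 1 fall among 21 (10 and 3 over the list alone; median 0.32, percentile 99.74). The endodermal genes CASP5 (1.45) and CASP1 (1.07) rose, and the iron transporter gene IRT1 fell (-2.68). Among 27 SWI/SNF subunit genes 3 fell and 1 rose (3 and 1 over the list alone; median -0.05, percentile 20.89). SYD itself fell, as did the merged locus of AT3G03460 and CYP89A9 (-0.90), and AT5G55040 rose (0.42). Of 15 Polycomb and trithorax genes 1 rose and 0 fell (1 and 0 over the list alone; median 0.07, percentile 69.6), and of 13 reference genes 1 rose and 1 fell (1 and 1 over the list alone; median 0.04, percentile 84.48).

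The comparison of the unlabelled condition with WT gave similar leading genes. In the authors' deposited table ASN1 rose from 1.12 to 164.9 FPKM (6.29), SEN1 from 21.6 to 596 (4.72), PHI-1 from 3.06 to 85.1 (4.41) and TCH4 from 19.2 to 352 (4.13). LTP4, a lipid transfer protein gene (4.101), HAK5 (3.92), AT4G12735 (3.56) and EXO (3.54) followed. The largest falls were AT2G30766 (-4.85), MIR157c (-4.70), AT5G05250 (-3.45), AT1G47395 (-3.28), LSU3 (-3.26), the merged locus of U12 and AT1G61280 (-3.21) and NAS1 (-3.21). NAS1, a nicotianamine synthase gene involved in iron transport, fell from 183.8 to 19.0 FPKM. AGL24 came next, at -3.06. The log2 ratio of AT2G30766 had an implied standard error of 2.18, so the size of its fall is uncertain. AT1G47400 stood at 0.310 FPKM against 19.95 in WT, a log2 fold change of -4.00 that did not pass the threshold (q = 0.142). In all, 5178 of 18450 tested loci passed q < 0.05, or 28.1%. Of these, 2529 rose, with a median of 0.70, and 2649 fell, with a median of -0.65. A doubling was reached by 685 and a halving by 566.

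Among hormone genes in the unlabelled condition, the authors' deposited table gave 14 rises and 0 falls among 22 jasmonate genes (14 and 0 over the list alone; median 0.49, percentile 100). VSP2 rose by 2.98 and JAZ5 by 1.57, and JAZ8, listed at 0 in WT, stood at 1.48 FPKM (q = 0.000567). Abscisic acid and cold loci had 8 rises and 2 falls among 16 (8 and 2 over the list alone, median 0.31, percentile 99.65), with COR15A at 2.78, RAB18 at 1.48 and KIN2 at 1.44. The merged locus of RD29A and RD29B was 1 of the rises. Auxin genes had 7 falls and 5 rises among 24 (8 and 6 over the list alone; median -0.36, percentile 0.01). Over the 15 that reached 5 FPKM the median was -0.10, at percentile 26.78. GH3.3 (2.60), SHY2 (1.24) and LBD16 (1.02), a lateral root gene, were among the rises. Of 14 gibberellin genes 6 fell and 2 rose (8 and 2 over the list alone; median -0.44, percentile 0.03), with GA3OX1 at -1.18, GA20OX2 at 1.14 and GA3OX2 at -1.06. Cytokinin response genes had 4 rises and 2 falls among 12 (4 and 3 over the list alone; median 0.06, mean -0.09, percentile 68.25), with RR16 at -2.58, CKX4 at -1.25 and ARR6 at 0.84. Ethylene genes had 5 falls and 2 rises among 13 (5 and 2 over the list alone; median -0.18, percentile 13.07), with ORA59 at 1.14 and PR4 at -1.02. In the salicylic acid and immunity list 7 rose and 6 fell among 22 (8 and 6 over the list alone; median -0.02, mean 0.20, percentile 40.61), with PR5 at 2.24, PR1 at 2.17 and the immune receptor gene SNC1 at -0.89. Brassinosteroid genes had 2 rises and 2 falls among 6 (2 and 2 over the list alone; median 0.12, percentile 74.94), with DWF4 at 0.91, BR6OX1 at 0.52 and BR6OX2 at -0.50.

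Of the developmental lists in the unlabelled condition, the stomatal lineage genes had 9 falls and 1 rise among 15 in the authors' deposited table (10 and 1 over the list alone; median -0.89, percentile 0). Root markers had 9 rises and 2 falls in this comparison (median 0.32, percentile 99.87). SPCH fell by 1.70, EPF2 by 1.48 and SDD1 by 1.11. Meristem and leaf polarity genes had 7 falls and 7 rises among 20 (7 and 7 over the list alone; median -0.09, percentile 18.06), with KAN at 1.07, TCP4 at -0.87 and TCP2 at -0.85. Cell cycle and DNA replication genes had 9 falls and 0 rises among 25 (10 and 0 over the list alone; median -0.16, percentile 3.39, but 2.1 with a filter of 5 FPKM, 1.92 with quantile normalization and 1.85 over loci with 1 gene name), with the DNA replication clamp gene PCNA1 at -1.09, MCM2 at -0.98 and TSO2 at -0.98. Flowering time genes had 2 rises and 1 fall among 13 (2 and 1 over the list alone; median 0.25, percentile 97.12, but 98.43 with quantile normalization). FLC rose from 3.89 to 15.6 FPKM (1.76), MAF5 rose by 1.65, and AGL24 was the fall. Floral organ identity had 1 rise among 4 (1 over the list alone), with a median of 0.69 (percentile 98.66), but 0.26 (percentile 86.82) with no filter. Seed maturation had 1 rise among 4 tested of 20 members (2 over the list alone, median 0.83, percentile 99.38). Of the tested genes, CRU1 (0.11 FPKM in WT, 2.60 in the unlabelled condition) and CRU3 (0.01 and 1.16) passed the filter only through the unlabelled condition. The filter thus favours a rise in this list, and its median and percentile give no support for one. Vegetative phase change had 3 rises among 11 and 0 falls (3 and 0 over the list alone; median 0.11, percentile 70.89), with SPL2 at 1.0997, SPL4 at 0.88 and SPL10, merged with RIC2, at 0.45.

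Among the stress and metabolic lists in the unlabelled condition, heat shock genes had 9 rises and 0 falls among 16 in the authors' deposited table (11 and 0 over the list alone; median 0.91, percentile 100), with HSP70 at 1.98, the merged locus of AT5G51440 at 1.62 and that of HSP90.1 at 1.51. Flavonoid and anthocyanin genes had 8 falls and 1 rise among 16 (8 and 1 over the list alone; median -0.57, percentile 0), with MYB111 at -1.98, FLS1 at -1.66 and TT7 at -1.53. Glucosinolate loci had 10 rises and 2 falls among 18 (11 and 2 over the list alone; median 0.43, percentile 99.98), with MAM1 at 1.27, FMO GS-OX1 at 1.02 and the merged locus of MYB29 and MYB76 at 1.02. Light harvesting and Rubisco genes had 9 rises and 3 falls among 22 (10 and 4 over the list alone). Their median was 0.10 (percentile 99.36), but 0.03 (percentile 97.225) with a filter of 5 FPKM. LHB1B1 stood at 2.49 and LHB1B2 at 1.64, 2 near-identical genes whose loci have the same span in the table and whose values are uncertain, and LHCB4.3 fell by 1.03. Clock genes had 1 rise and 4 falls among 19 (1 and 6 over the list alone; median -0.13, percentile 16.13), with PCL1 at 1.06, RVE8 at -0.98 and ELF4 at -0.92. Root markers had 9 rises and 2 falls among 21 (11 and 2 over the list alone; median 0.32, percentile 99.87), with IRT1 at -2.68 and CASP5 at 1.28. SWI/SNF subunits had 2 falls and 1 rise among 27 (2 and 1 over the list alone; median -0.05, percentile 26.0), with SWI3D at -1.86, the locus of AT3G03460 at -0.99 and AT5G55040 at 0.43. Polycomb and trithorax genes had 1 rise and 1 fall among 15 (1 and 1 over the list alone; median 0.06, percentile 73), and reference genes 1 and 1 among 13 (0 and 1 over the list alone; median -0.03, percentile 77.55).

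**Figure D2:**
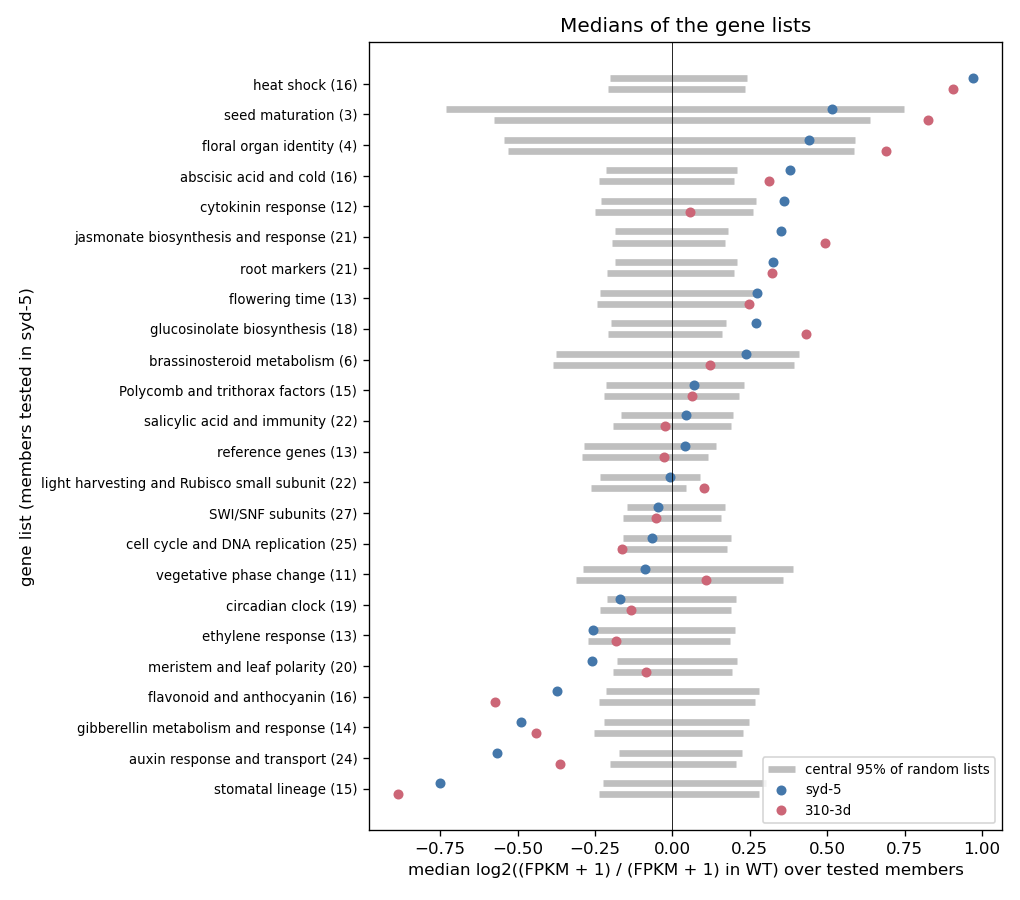
Median log2 fold change against WT over the tested members of each of the 24 gene lists (horizontal axis, log2 of the ratio of FPKM + 1), for syd-5 in blue and the unlabelled condition in red under its name in the table, with the number tested in syd-5 after each name. Grey bars span the central 95% of the medians of 10000 random lists matched on expression, and heat shock (0.97 and 0.91) and stomatal lineage (-0.75 and -0.89) lie outside them in both conditions.

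The next comparison asks whether both conditions changed the same genes. In the authors' deposited table, 2053 loci rose in both and 2118 fell in both, among 18419 loci tested in both, and 0 went in opposite directions. Independent lists of the same sizes would share 348 rises and 373 falls. Of the rises in syd-5, 80.6% were called in the unlabelled condition too, and of the falls 81.7%. A further 968 loci were called in syd-5 and not in the unlabelled condition, and 998 the reverse, which does not show that they differed. Across loci, which are not independent replicates, the Pearson correlation of the log2 fold changes was 0.925. Both conditions were set against the same WT values, so part of this excess may come from them. Among 14096 loci with a mean of at least 5 FPKM, the correlation without a pseudocount was 0.944 and the covariance 0.350. Simulated unchanged conditions, in which WT supplied an equal share of the implied variance, gave a mean correlation of 0.499, which follows from that share. They gave 14.4 loci called the same way, against 3413 observed. With no effect in either condition they had only 147.4 and 147.1 calls, against 4113 and 4167 observed. The simulated overlap could therefore not come near 3413, and it does not test how much of the overlap comes from WT. The simulated covariance was 0.0264 with errors on the scale of the authors' p, and 0.0800 with the larger errors of the statistic itself. The WT values could not be split, because the table gives 1 pooled value.

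**Figure D3:**
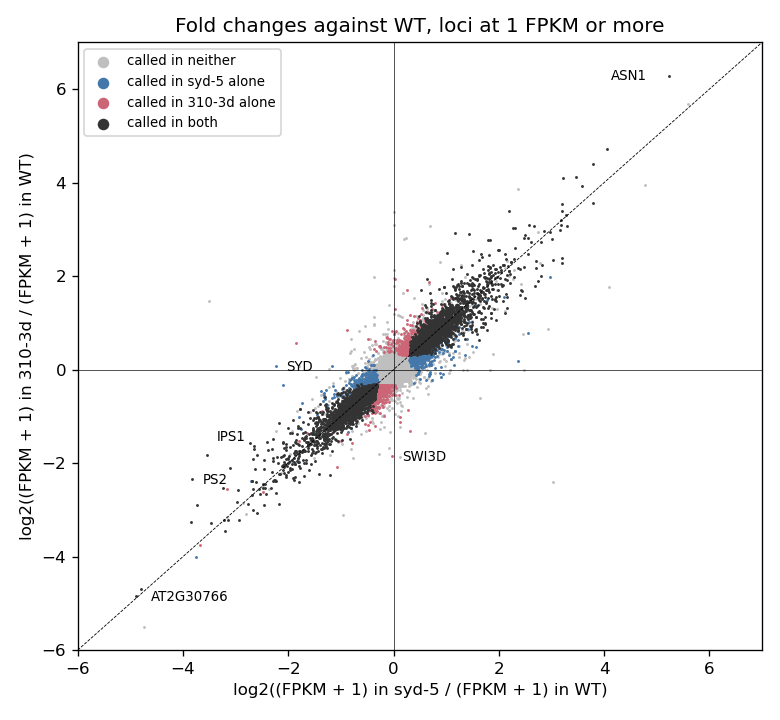
Log2 ratio of FPKM + 1 to WT in syd-5 (horizontal axis) and in the unlabelled condition (vertical axis, under its name in the table), 1 point per locus at 1 FPKM or more, coloured by where the authors' q was under 0.05, with a dashed line of equal change. The 4171 loci called in both fell in both or rose in both, and SYD and SWI3D lie away from the line.

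The last comparison sets the unlabelled condition against syd-5, for which the authors' deposited table used here holds no test. A test of the difference between the log2 ratios, built from the authors' statistics and chosen after the data were seen, found 17 of 18382 loci at a Benjamini-Hochberg adjusted p under 0.05, with 11 higher and 6 lower in the unlabelled condition. An unadjusted p under 0.05 was found for 415. This count cannot be read against the threshold itself, since the test counts the WT error in both ratios. In the simulated data, 0.55% of unchanged loci had such a p with changes of 1 in log2, and 0.572% with changes of 2. The simulated noise had the errors that the test assumes. Of the 17, 13 had a mean of at least 5 FPKM. Among these 13, SYD (a log2 difference of 2.56), IPS1 (1.99), the plastid gene ATCG00020 (1.96), PS2 (1.86) and the merged locus of AT2G28755 and UXS6 (1.36) were the furthest above syd-5 in the unlabelled condition. SWI3D (-2.07), CYP82F1 (-1.24), AT1G73600 (-1.07) and PCR1 (-0.96) were lower in the unlabelled condition. PCR1 had 44.5 FPKM in WT, 82.9 in syd-5 and 42.6 in the unlabelled condition. With the larger standard errors of the statistic itself the count was 3, namely SYD, SWI3D and ATCG00020, so the other differences rest on the scale of the authors' p. With the error enlarged at each locus whose own p called for it, 14 of the 17 passed, 10 higher and 4 lower.

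Of the 24 lists, 4 had a median difference between the unlabelled condition and syd-5 above the central 95% of random lists and 3 below it, a description of these values and not a test. Above it were auxin (0.28, percentile 100), light harvesting and Rubisco (0.22, percentile 100), meristem and leaf polarity (0.12, percentile 99.93) and gibberellin (0.08, percentile 97.95, but 97.28 with no filter). Below it were cytokinin response (-0.25, percentile 0), salicylic acid and immunity (-0.16, percentile 0.02) and flavonoid and anthocyanin (-0.15, percentile 0.63). The remaining 17 lists lay within it. Of these, the cell cycle list (-0.07, percentile 4.39) lay below it with a filter of 5 FPKM (percentile 0.81), quantile normalization (2.47) and loci with 1 gene name (0.36). Over loci with 1 gene name, heat shock (percentile 99.41), seed maturation (99.8) and vegetative phase change (97.7) lay above it. The heat shock median turned there from -0.09 (percentile 3.73) to 0.13. The seed maturation value there rests on 2 genes, CRU1 and CRU3, which reached 1 FPKM only in the unlabelled condition. Apart from SYD and SWI3D in the list of SWI/SNF subunits, 0 list members differed between the conditions by the test above when p was adjusted over all loci. Adjusted over the list alone, 2 light harvesting and Rubisco genes and 3 ethylene genes were higher in the unlabelled condition, and 1 gene each was lower in the salicylic acid, cytokinin and heat shock lists.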

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

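The test between the unlabelled condition and syd-5 and its error scales were chosen after the data were seen. No outlying library could be looked for, since the table has no value per library. The log2 ratio to WT differed between the unlabelled condition and syd-5 at 13 loci with a mean of at least 5 FPKM, and the values are the ratio in the unlabelled condition minus that in syd-5. The targeted genes had the clearest differences, SYD at 2.56 (adjusted p on the scale of the statistic itself 1.43e-10) and SWI3D at -2.07 (0.00269). The plastid gene ATCG00020 differed by 1.96 (0.00348), with 30.8 FPKM in WT, 31.3 in syd-5 and 122 in the unlabelled condition. The other 10 did not pass on that scale. They were the merged locus of AT2G28755 and UXS6 (1.36), AT2G20670 (0.84), CYP82F1 (-1.24), AT1G73600 (-1.07), PCR1 (-0.96) and the 5 phosphate genes below. All 13 passed when the error was enlarged at each locus whose own p called for it. Of all 17 loci that differed, 3 did not pass then, namely AT1G07175, AT3G01940 and a locus without a gene name, each with a mean under 5 FPKM.

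The phosphate starvation genes IPS1 (1.99), PS2 (1.86), PEPC1 (1.15), SPX1 (1.05) and G3Pp1 (0.88) fell in both conditions and further in syd-5. Selection of the genes with the largest difference is argued against by 13 other phosphate genes, whose median difference was 0.31, at percentile 100 of matched random lists. A weaker overall response in the unlabelled condition is argued against too, since the 2118 loci lower in both had a median difference of 0.00109. A difference in phosphate supply between the growths of the plants, or a difference between the plants of both conditions in genotype, stays open and was not tested, since these genes are co-regulated and the table has no replicates.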

How the results depend on the processing

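The adjustment within each comparison, loci with 1 gene name, ratios without a pseudocount and the other error scales were chosen after the data were seen. No paired analysis was possible because the table holds 1 pooled value per condition and none per replicate. For the same reason leaving out each library, fits of 6 libraries, the replicate block, camera, other splits of the samples and count-based tests were not run, and the authors' own calls are the main result. No setting turned the direction of a called gene, or of a list whose median lay outside the random range with the main settings. The pseudocount does not enter the calls, and quantile normalization shifted the fold changes by a median of -0.01 in syd-5 and -0.000375 in the unlabelled condition. With no filter, the filter of 5 FPKM or q < 0.01, the counts against WT and the shared count stayed within 1.5 times, and the correlation lay between 0.911 and 0.940 over the planned settings and was 0.944 without a pseudocount at loci with a mean of at least 5 FPKM.

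Adding a doubling or halving left 1251 loci in syd-5 (671 up, 580 down), 1251 in the unlabelled condition (685 up, 566 down) and 960 shared, because it leaves fewer loci by construction. Adjusting within each comparison gave 1 locus called in opposite directions, where the authors' q gave 0. Between the unlabelled condition and syd-5, the scale of the statistic itself left 3 loci (2 higher, 1 lower) of 17, and adjusted p under 0.01 left 6 of the 11 higher. With loci of 1 gene name, 8 lists in syd-5 lay below the random range, not 5, and 7 lists between the unlabelled condition and syd-5 lay above it, not 4. With these loci 9 list medians left the random range and 0 came back into it. They were cell cycle in all 3 comparisons, ethylene, clock and light harvesting in syd-5, and the differences of vegetative phase change, seed maturation and heat shock. Of these, light harvesting in syd-5 turned from -0.01 to 0.12 and the heat shock difference from -0.09 to 0.13. Other settings brought list medians back into the random range, 4 with no filter, 4 with the filter of 5 FPKM and 1 with a pseudocount of 0.1, while 0, 4 and 2 left it. Those that left were cell cycle in all 3 comparisons (-0.19, -0.19 and -0.10) and floral organ identity in syd-5 (1.32) with the filter of 5 FPKM, and floral organ identity (1.32) and seed maturation (1.71) in syd-5 with a pseudocount of 0.1. Flowering time in syd-5 came back under each of these 3 settings, and the gibberellin difference under both filter settings. The others were floral organ identity in the unlabelled condition (from 0.69 to 0.26) and meristem and leaf polarity in syd-5 (from -0.26 to -0.15) with no filter, and auxin (from -0.36 to -0.10) and light harvesting and Rubisco (from 0.10 to 0.03) in the unlabelled condition with the filter of 5 FPKM. With quantile normalization 0 list medians came back and 3 left the range, namely flowering time and cell cycle in the unlabelled condition and the cell cycle difference. The cause of these changes was not tested. Of the named genes' comparisons with WT, 10 lost their call at q < 0.01 and 64 had no doubling or halving. Depth is unknown. In 5 equal classes of mean FPKM, 23.0% of the lowest class were called in syd-5 and 32.7% of the highest.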

Other observations

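Lists in this part were drawn up after the leading genes were seen and before the values of their other members were, and the genes that prompted each list were left out of its test. The test of shared WT noise and that of root tissue were chosen after their results were seen. Other members of nutrient deficiency lists fell in both conditions in the authors' deposited table. Of 14 iron deficiency genes 9 fell and 1 rose in syd-5 (median -0.95) and 8 fell and 2 rose in the unlabelled condition (-1.06). The iron transporter genes IRT1 (-2.68 in both) and OPT3 (-2.43 and -2.66) were among the falls. Of 13 phosphate starvation genes 11 fell and 1 rose in each condition (medians -1.26 and -0.997), with PAP17 at -2.09 and -1.56. Of 12 sulphur deficiency genes 10 fell and 1 rose in each (-1.33 and -1.55), with LSU2 at -2.47 and -2.13 and the sulphate reductase gene APR3 at -1.87 and -2.01. Each of the 3 medians lay at percentile 0 of matched random lists in both conditions. Of 17 genes of sugar starvation and darkness 15 rose and 0 fell in each (medians 1.101 and 1.12, percentile 100 in both), with DRM2 at 1.63 and 1.83 and BCAT2 at 2.23 and 2.297. A harvest of WT at another time of day, examined below with clock genes alone, was not tested as a source of this rise. The hypothesis that touch response genes rose as a group was not borne out. Without TCH4, XTR6, EXO and PHI-1, which prompted it, the median of 11 genes was -0.45 in syd-5 (percentile 0.13) and 0.00 in the unlabelled condition (percentile 62.71).

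The fall of the deficiency genes may have a technical source. A smaller share of root tissue is argued against by the root markers, whose median was 0.32 in both conditions, above 0. That test was chosen after its result was seen, and the root marker IRT1 is itself among the falling iron deficiency genes. A pattern made by the prompting genes alone is argued against by the 39 other members of the 3 lists, with medians of -1.20 and -1.16 at percentile 0 in both conditions. Better supplied growth medium, slower growth with less nutrient demand, and an effect of the conditions' genotypes on these regulons stay open and were not tested.

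The fold changes of syd-5 and the unlabelled condition move together. Noise of the shared WT values is argued against as the whole cause, since the covariance of 0.350 exceeded 0.160, the most that this noise could give on the scale of the statistic. The ratio of these values was 2.196, with a bootstrap 95% interval over loci of 1.96 to 2.43. Loci are not independent replicates, so this interval does not measure the spread between plants and may be too narrow. The rule for this test asked for more than a doubling of 0.160, which the lower end of the interval does not reach. A WT harvest at another time of day cannot be told apart from an effect of the conditions. Morning clock genes stood below evening clock genes by a difference of -0.31 in median log2 fold change in each condition, between the bounds of 0.2 and 0.5 set in advance, and members of both sets went both ways. Any other difference in how the WT plants were grown, and an effect common to both conditions, stay open and were not tested.

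The share of calls around SYD and SWI3D lay within that of other windows. Within 2 Mb of SYD 30.9% of 689 loci were called in syd-5, at percentile 82.4 of 196 windows of that size, and percentile 85.7 in the unlabelled condition. Within 2 Mb of SWI3D 27.0% of 810 loci were called in the unlabelled condition, at percentile 19.9, and percentile 15.3 in syd-5.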
